A study of Eulophia maculata with 6 samples.

How the data were processed

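Root sections of the terrestrial orchid Oeceoclades maculata (listed by GEO as Eulophia maculata), collected in nature, were sequenced as 6 RNA libraries. 3 libraries came from mycorrhizal roots of 3 adult plants and 3 from non-mycorrhizal roots of 3 other plants. Per the labels, total RNA was extracted with TRIzol. FastQC is the only program the labels name, and its version, the assembler and the read mapper are not given in the sources used here.

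The deposited table lists 78135 assembled contigs of 200 to 16788 bases, with a median length of 430 bases. Per the file headers, its values are counts of trimmed, merged paired reads per contig, as total reads and as uniquely mapped reads, and no normalization was applied to them. The contig length in bases is a further deposited column of another unit and was used only to describe contigs. Total reads were analysed. RPKM values and the authors' own test columns were not used here. Annotation in the table comes from SwissProt matches handled in Blast2GO. A SwissProt accession stood on 47818 contigs and product text on 12739, or 15109 after contigs with the same accession shared their text. No read was counted for 180 contigs in any library.

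Total counts were 11485386, 10497990 and 10186582 in non-mycorrhizal replicates 1, 2 and 3, and 9401338, 12304820 and 11013482 in mycorrhizal replicates 1, 2 and 3. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Contigs were kept by filterByExpr with its default settings, which left 23213, and libraries were scaled by TMM, with factors from 0.898 to 1.10. One model without a block was fitted, and edgeR's quasi-likelihood test, two-sided, was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are mycorrhizal over non-mycorrhizal, and their standard error is the log2 fold change divided by the square root of the F statistic. Expression levels are TMM-scaled CPM, the counts scaled to libraries of a common size, given as mean ± SD with n = 3. Where a group had no read, the fold is a lower bound computed against 3 counts over the group. Where it had 1 to 3 reads, the ratio of the groups is given with its exact 95% counting interval. Other folds are fitted. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

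The following were chosen before the data were examined: the main test, the alternatives except those named as added, 29 gene lists defined by patterns in the annotation text, and the rule for named contigs. That rule took contigs past the threshold with a mean of at least 5 CPM, no overlap between groups and a product name, fungal contigs apart, and from these, with 1 contig per product name, the 10 with the largest change in each direction. It also took the 5 fungal contigs with the highest mycorrhizal level, up to 2 contigs per direction of each list by smallest adjusted p, and the 3 most abundant reference genes. Lists were tested with camera in limma at a preset correlation of 0.01, two-sided, adjusted over the 29 lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way and does not compare it with other genes, were alternatives. The patterns also match alternative names in the annotation, so some members do other work than the list's name says.

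The fungal share was the percent of a library's counts on contigs whose best SwissProt match is a fungal protein, with an exact Clopper-Pearson 95% interval per library and an exact two-sided permutation test. Fungi were recognised by 89 species codes of SwissProt entry names, written after the codes in the table were seen. Entry names stood only in the product text, so only the 15109 contigs with such text could be recognised as fungal. Contigs with an accession alone were counted as not fungal.

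Added after seeing the data were uniquely mapped reads, a Fisher's exact test, one-sided, of Gene Ontology biological process terms with at least 10 contigs, and 7 lists. These lists were beta-1,3-glucanases, whose names had lost characters in the table, DNA replication, mitosis and cytokinesis, histones, root meristem identity, root cap, and retrotransposon polyproteins. The mitosis and histone patterns were narrowed after their members were seen, since they had matched ketoacyl-CoA synthases and histone methyltransferases. The root cap list had fewer than 3 tested contigs and was not tested. Added lists were adjusted among themselves.

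Alternatives were DESeq2 1.42.0 size factors, library size alone, TMM from contigs not annotated to fungi, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, a block on replicate number, a 2-fold threshold, fungal contigs left out, and each library left out in turn. The procedure was tested on simulated data made from these libraries with 200 changed contigs among 22632: it recovered 25 of 100 contigs changed 2-fold and 80 of 100 changed 4-fold, with 14 false calls. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.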

Results

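RNA of roots of the orchid Oeceoclades maculata was sequenced in 3 mycorrhizal and 3 non-mycorrhizal libraries, each group from 3 adult plants. Total counts per library ranged from 9401338 in mycorrhizal replicate 1 to 12304820 in mycorrhizal replicate 2. The first principal component of log2 CPM held 66.5% of the variance and separated the groups, and the second held 12.5%. Mycorrhizal replicate 1 lay farthest from the non-mycorrhizal libraries on the first component, at 97.6, with the other 2 mycorrhizal libraries at 60.1 and 54.2. Across contigs, which are not independent replicates, Pearson correlations of log2 CPM between libraries were 0.952 to 0.983 within groups and 0.864 to 0.924 between groups. Transcripts are named by contig number and by the product of their best SwissProt match.

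The comparison of mycorrhizal with non-mycorrhizal roots asks how metabolism and defence differ when a root holds its fungus. Transcripts of hydrolases, amino acid permeases and a stilbenoid enzyme stood among the largest increases in mycorrhizal roots. Vacuolar-processing enzyme (contig 2627, 2164 bases), a protease of the vacuole, rose 41.3-fold, from 10.3 ± 3.16 to 428 ± 82.1 CPM (SD, n = 3; edgeR adjusted p = 0.000122). Beta-glucosidase 18 (contig 7982, 1746 bases) rose 284-fold, from 0.13 ± 0.113 to 41.3 ± 14.7 CPM (edgeR adjusted p = 0.000195). The KDEL-tailed cysteine endopeptidase CEP1 (contig 33935, 1272 bases), of a protease family known from programmed cell death, reached 12.8 ± 2.86 CPM in mycorrhizal roots and had no read in non-mycorrhizal roots, a rise of at least 126-fold (edgeR adjusted p = 0.000623). That bound was 81.5 without non-mycorrhizal replicate 1. Germin-like protein 2-1 (contig 7408, 1005 bases) rose 62.0-fold to 189 ± 72.6 CPM, and 104-fold without non-mycorrhizal replicate 1.

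Bibenzyl synthase (contig 15481, 1562 bases), which makes stilbenoids of orchids, was 109-fold higher by the ratio of counts (95% counting interval 37 to 531), and 218-fold higher without non-mycorrhizal replicate 3 (interval 38.9 to 8640). Probable amino acid permease 7 (contig 2486) rose 89.5-fold, or 54-fold without mycorrhizal replicate 1. Amino acid permease 1 (contig 9210) rose 44.5-fold, or 106-fold by the ratio of counts without non-mycorrhizal replicate 3 (interval 29.3 to 883). Scarecrow-like protein 32 (contig 8822), a GRAS-family transcription factor, rose 45.0-fold and an anthocyanin glucosyltransferase (contig 16887) 37.1-fold. A polyprotein contig of the Tnt1 retrotransposon type (contig 5246) was 512-fold higher by the ratio of counts (interval 142 to 4240). The 10 contigs named here, 1 per product name, had edgeR adjusted p between 0.000122 and 0.00148.

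Among the largest decreases in mycorrhizal roots were a lipid-transfer protein, a receptor-like kinase, a replication factor and 2 subtilisin-like proteases. MCM2 (contig 73187, 3177 bases), a subunit of the replicative helicase, fell 117-fold from 14.97 ± 7.22 to 0.114 ± 0.0382 CPM (SD, n = 3; edgeR adjusted p = 0.00047). A receptor-like protein kinase (contig 24152, 2702 bases) fell 220-fold from 79.9 ± 23.5 CPM (edgeR adjusted p = 0.000122), or 365-fold without mycorrhizal replicate 1. The lipid-transfer protein DIR1 (contig 73649, 569 bases), known from systemic acquired resistance, fell from 30.4 ± 23.7 CPM to no read, at least 358-fold (edgeR adjusted p = 0.00418). That bound was 198, 226 and 238 without non-mycorrhizal replicate 1, mycorrhizal replicate 2 and mycorrhizal replicate 3. Fasciclin-like arabinogalactan protein 13 (contig 35482), a cell wall protein, was 133-fold lower by the ratio of counts (interval 45 to 646), and 83.4-fold lower without non-mycorrhizal replicate 1 (interval 28 to 409).

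Calreticulin (contig 49461, 1596 bases), a calcium-binding chaperone, had 459.5, 110 and 27.4 CPM in non-mycorrhizal replicates 1, 2 and 3 and 0.0869 ± 0.151 CPM in mycorrhizal roots. Its ratio of counts was 2362 (interval 808 to 11500), and it was 774 (264 to 3760) without non-mycorrhizal replicate 1, 1490 (510 to 7230) without mycorrhizal replicate 2 and at least 1570 without mycorrhizal replicate 3. A subtilisin-like protease (contig 56278), the subtilisin-like protease SDD1 (contig 73660), PNGase A (contig 70941), a branched-chain aminotransferase-like protein (contig 43943) and cytochrome P450 71D7 (contig 40636) completed the 10, taken as 1 contig per product name, with edgeR adjusted p between 0.00524 and 0.0179. The calls on calreticulin, SDD1 and PNGase A ended with limma-voom, at adjusted p of 0.0531, 0.0506 and 0.0646. Calreticulin and these 5 contigs shared an unequal level among the non-mycorrhizal libraries. Of 74 contigs at least 16-fold lower in mycorrhizal roots with a non-mycorrhizal mean of at least 5 CPM, 30 had a log2 ratio of non-mycorrhizal replicate 1 over replicate 3 above 2.5. Their median ratio was 13.1 over replicate 3 and 4.13 over replicate 2. All 30 still passed the edgeR test without non-mycorrhizal replicate 1.

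**Figure D1:**
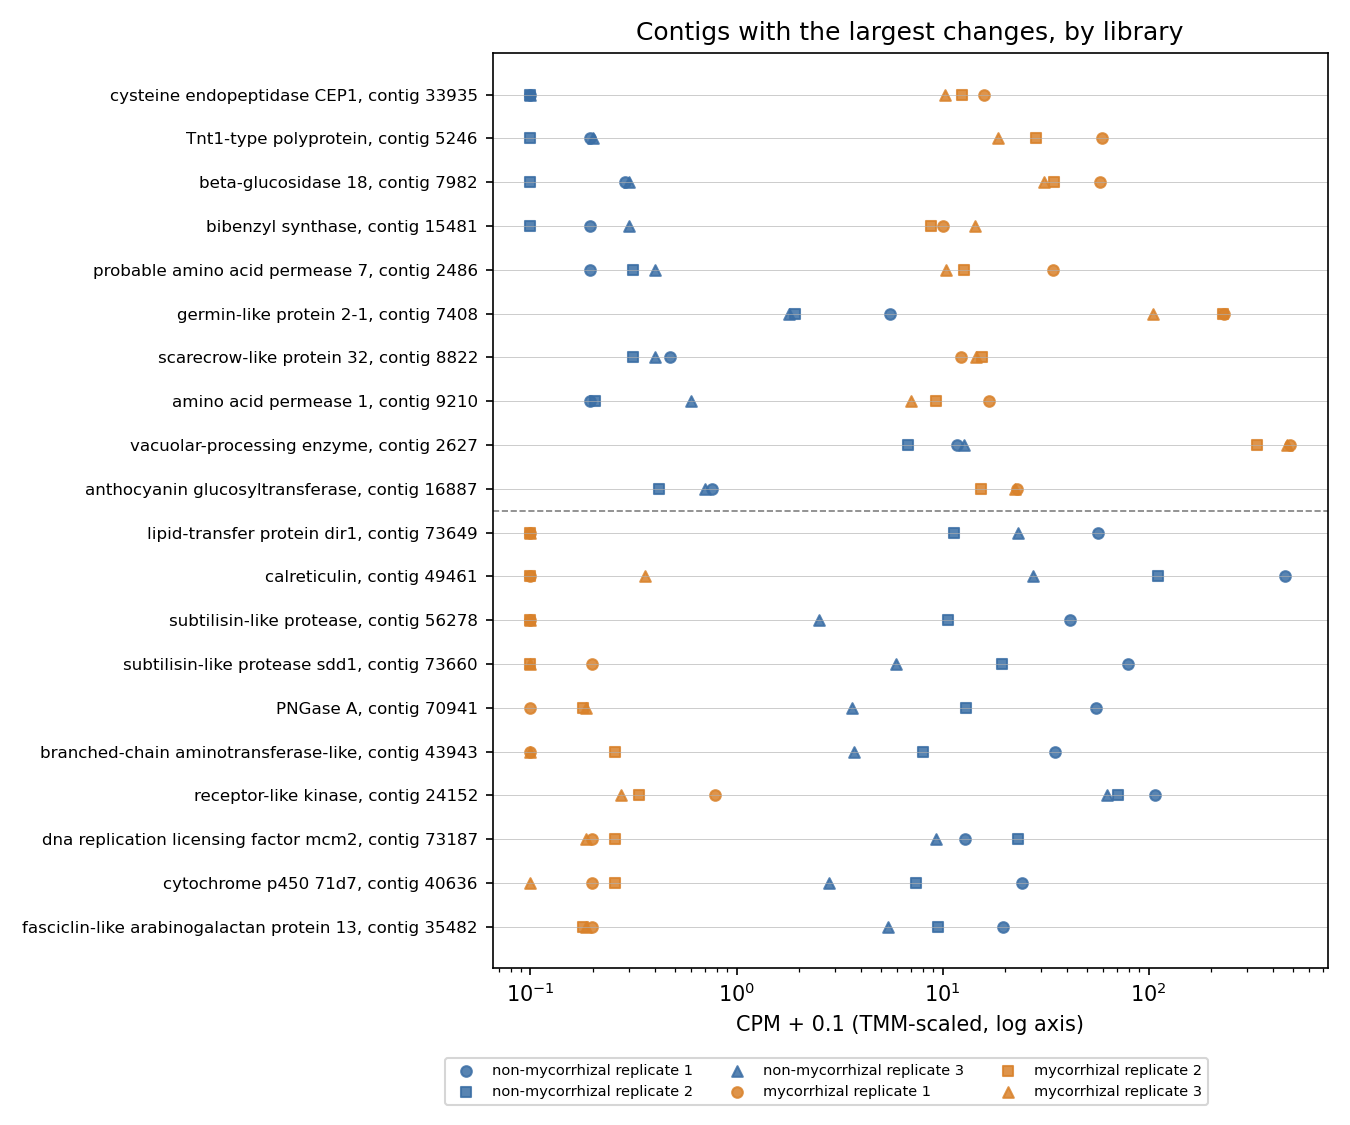
TMM-scaled CPM plus 0.1, on a log axis, of the 10 named contigs with the largest increase (above the dashed line) and the 10 with the largest decrease, taking 1 contig per product name and leaving out fungal contigs, one point per library, with 3 mycorrhizal and 3 non-mycorrhizal libraries. The groups do not overlap for any of these contigs, which were chosen for that, and calreticulin has 459.5, 110 and 27.4 CPM in non-mycorrhizal replicates 1, 2 and 3.

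**Figure D2:**
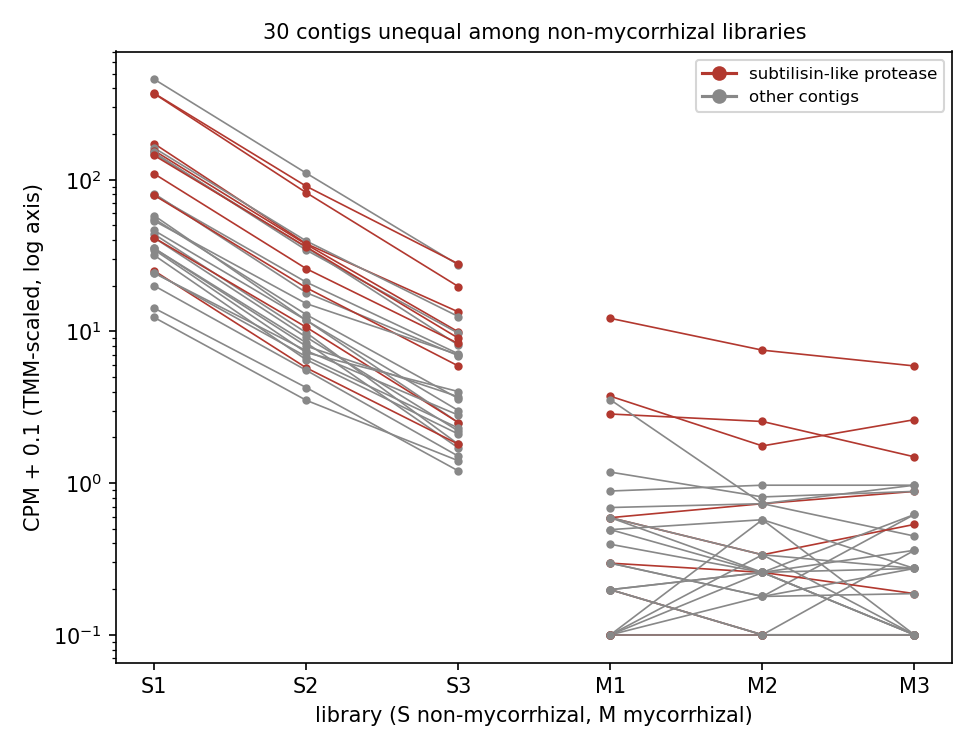
TMM-scaled CPM plus 0.1, on a log axis, in the 3 non-mycorrhizal (S) and 3 mycorrhizal (M) libraries for the 30 contigs at least 16-fold lower with unequal non-mycorrhizal levels; lines only join the values of a contig, since replicates have no order. The lines between the non-mycorrhizal libraries run nearly parallel, with a median ratio of 13.1 for replicate 1 over replicate 3, and 9 contigs are subtilisin entries.

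Of 23213 contigs tested, 2424 rose and 2573 fell in mycorrhizal roots by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 914 and 1289 of these have product text. At least 2-fold changes made up 1732 of the rises and 1397 of the falls, and at least 16-fold changes 124 and 111. The groups did not overlap for 10352 contigs (44.6%), where chance gives 10%. With library size alone in place of TMM, 3809 rose and 1693 fell, since that scaling moves the median log2 fold change by 0.184; the directions given here are relative to TMM. The counts rest on the libraries used: 1601, 789 and 1047 rose without non-mycorrhizal replicates 1, 2 and 3, and 1150 and 1653 fell without non-mycorrhizal replicates 2 and 3. Called in the same direction in all 6 fits that leave out a library were 649 of the rises and 984 of the falls.

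Contigs recognised by a fungal best match took a small share of the counts in both groups. Only contigs with product text, which held 56.5% to 61.0% of a library's counts, could be recognised. Fungal matches among the other contigs were missed. The best match does not show that a contig is fungal, since a conserved plant gene can match a fungal protein best, and 44 of the 57 such contigs tested had a mean of at least 1 CPM in non-mycorrhizal roots. Their share was 0.185% ± 0.00552 in mycorrhizal and 0.157% ± 0.00787 in non-mycorrhizal roots (SD, n = 3), a difference of 0.0274 percentage points, with exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. Over annotated contigs alone the difference was 0.0601 percentage points, at the same p. Non-mycorrhizal replicates 1, 2 and 3 held 0.153% (95% Clopper-Pearson interval 0.151 to 0.156), 0.152% (0.15 to 0.155) and 0.166% (0.164 to 0.169). Mycorrhizal replicates 1, 2 and 3 held 0.19% (0.188 to 0.193), 0.179% (0.177 to 0.182) and 0.185% (0.182 to 0.187). All 3 mycorrhizal libraries lay above all 3 non-mycorrhizal libraries, and the mean share was 1.17 times as high. The share is taken of all counts without TMM, and library size alone moves the median log2 fold change of the tested contigs upward by 0.184. The difference thus need not come from fungal RNA. Of the 44 contigs named above, 0 were called higher.

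The 5 contigs with a fungal match and the highest level in mycorrhizal roots were present in both groups and did not pass the edgeR test. These were an Xaa-Pro aminopeptidase (contig 3982, 113 ± 8.28 CPM in non-mycorrhizal and 146 ± 7.28 in mycorrhizal roots, adjusted p = 0.063), the splicing factor CWC22 (contig 3835, adjusted p = 0.555), the transport protein SEC23 (contig 284, adjusted p = 0.768), the isomerase CYP5 (contig 7475, adjusted p = 0.0526) and the folate synthesis protein FOL1 (contig 1055, adjusted p = 0.621). Contigs 3982 and 7475 passed with the DESeq2 Wald test, at adjusted p of 0.0459 and 0.0348. Of 57 tested contigs with a fungal match, 13 rose and 4 fell. The 13 that rose all had a mean below 0.25 CPM in non-mycorrhizal roots, and 6 of them had no read there. The filter keeps a contig this low there only if its mycorrhizal libraries are higher. The direction of these 13 was thus fixed by the filter. All 13 tested contigs with a fungal match and a non-mycorrhizal mean under 1 CPM rose.

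The examples of the 13 given here were chosen after their values were seen. Isocitrate lyase (contig 35095) reached 4.21 ± 2.34 CPM, malate synthase (contig 23390) 2.28 ± 0.736 CPM and phosphoenolpyruvate carboxykinase (contig 29343) 2.43 ± 0.552 CPM in mycorrhizal roots (SD, n = 3). Elongation factor 3 (contig 28486), a translation factor of fungi, had 6.66 ± 1.67 CPM against 0.232 ± 0.203 CPM (edgeR adjusted p = 0.00229). The others include a glutamine synthetase (contig 33927), an acyl-CoA desaturase (contig 21997), an aldehyde dehydrogenase (contig 22893) and a quinate permease (contig 54079), of which the call on the aldehyde dehydrogenase was lost on leaving out at least 1 library. A formate dehydrogenase (contig 18039) had 4.76 ± 1.61 CPM against no read (edgeR adjusted p = 0.00234). The 4 that fell, also chosen after their values were seen, were an ATG1-type kinase (contig 9790, from 106 ± 3.66 to 74.2 ± 5.55 CPM), a SEC23 pair (contigs 14698 and 21378) and an isomerase (contig 11280), and each call was lost on leaving out at least 1 library.

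Lectins, peroxidases and enzymes of lignin synthesis were lower in mycorrhizal roots as lists. The mannose-specific lectin of contig 1105 (1136 bases), of the monocot mannose-binding lectin family, fell 43-fold from 54100 ± 23310 to 1260 ± 734.8 CPM (SD, n = 3; edgeR adjusted p = 0.0025). It took 4.47%, 7.12% and 3.34% of all counts in non-mycorrhizal replicates 1, 2 and 3 and at most 0.21% in a mycorrhizal library. Of 5 tested lectins, 3 fell, and 4 did when adjusted over the list alone, with a median log2 fold change of -4.40 (camera adjusted p = 0.00488, and adjusted p = 0.485 with an estimated correlation). Of 28 class III peroxidases, 8 fell and 20 were not called (9 fell when adjusted over the list alone), among them peroxidase 17 (contig 20872, 3.68-fold) and peroxidase 5 (contig 12299, 2.47-fold). Their median was -0.58 (camera adjusted p = 0.00653, and adjusted p = 0.485 with an estimated correlation), but -0.18 without non-mycorrhizal replicate 1 and -0.96 without mycorrhizal replicate 3. In phenylpropanoid and lignin synthesis, 19 of 47 contigs fell, 2 rose and 26 were not called (21 and 4 when adjusted over the list alone). Shikimate O-hydroxycinnamoyltransferase (contig 14384), an early enzyme of the lignin branch, fell 3.98-fold and tricetin O-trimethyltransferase (contig 32881) 3.94-fold. The list's median was -0.70 (camera adjusted p = 0.000563, and adjusted p = 0.548 with an estimated correlation), and -0.32 without non-mycorrhizal replicate 1. Laccase-3 (contig 18191) and a further tricetin O-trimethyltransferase (contig 34503) belong to the 30 contigs with unequal non-mycorrhizal levels.

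Antioxidant enzymes had 15 of 59 contigs lower, 4 higher and 40 not called (17 and 4 when adjusted over the list alone), with superoxide dismutase (contig 29036) down 4.77-fold and glutathione S-transferase U24 (contig 16048) 2.67-fold. This list passed at camera adjusted p = 0.00194, and at adjusted p = 0.485 with an estimated correlation it did not. Of the 5 contigs in the list of chitinases and beta-glucanases, 2 fell and 3 were not called (3 fell when adjusted over the list alone). Both match chitinase-like protein 1, which is known for cellulose deposition and not for cleaving chitin. The fall was 13.1-fold in contig 22825 and 1.49-fold in contig 6761 (edgeR adjusted p = 0.0445). The call on contig 6761 was lost with a block on replicate number (edgeR adjusted p = 0.0666) and on leaving out at least 1 library. The list missed the threshold at camera adjusted p = 0.064 and passed at 0.0292, 0.00823 and 0.0183 without non-mycorrhizal replicates 2 and 3 and mycorrhizal replicate 1. Among 15 beta-1,3-glucanases, a list added after seeing the data, 9 fell, 1 rose and 5 were not called, with the same counts adjusted over the list alone. Contig 11971 of this group fell 3.80-fold and contig 5562 fell 2.21-fold, and the median was -0.76 (camera adjusted p = 0.000821, and adjusted p = 0.187 with an estimated correlation).

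Other defence lists went both ways. Of 28 pathogenesis-related and antimicrobial contigs, 5 rose, 6 fell and 17 were not called (6 and 10 when adjusted over the list alone; camera adjusted p = 0.308). Contigs whose best match is the asparagus entry named pathogenesis-related protein 1 rose 7.14-fold (contig 25020) and 7.08-fold (contig 6747), and fell 2.57-fold (contig 5984). The name of the match alone does not show which family of pathogenesis-related proteins they belong to. Of 31 immune receptors and their regulators, 6 rose, 3 fell and 22 were not called (7 and 3 when adjusted over the list alone; camera adjusted p = 0.512). NPR1 (contig 9106), the salicylic acid coactivator, rose 2.24-fold and RPM1-interacting protein 4 (contig 8966) fell 2.49-fold. In flavonoid and stilbenoid synthesis, 8 of 46 contigs rose, 6 fell and 32 were not called (9 and 6 when adjusted over the list alone; camera adjusted p = 0.11). An anthocyanidin glucosyltransferase (contig 7831) rose 13.4-fold, and isoflavone reductase homologs (contigs 3374 and 27063) fell 3.24-fold and 2.44-fold.

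As lists, nitrogen transporters were higher and aquaporins lower in mycorrhizal roots. Of 89 nitrogen transporters, 18 rose, 6 fell and 65 were not called (21 and 7 when adjusted over the list alone), with a median log2 fold change of 0.23 and the amino acid permeases of contigs 2486 and 9210 in the lead. The list passed at camera adjusted p = 0.027, but at adjusted p = 0.548 with an estimated correlation it did not. Nor did it without non-mycorrhizal replicates 2 and 3 (0.0501 and 0.131) or mycorrhizal replicates 2 and 3 (0.0558 and 0.0658), with a block on replicate number (0.0509) or with fry (0.0542). Of 25 contigs of nitrogen assimilation, 1 rose, 2 fell and 22 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.522). The rise was that of glutamate synthase (contig 1233), which makes glutamate from glutamine, at 3.32-fold from 155 ± 56.4 to 512 ± 189 CPM (edgeR adjusted p = 0.0106, n = 3). Of 28 aquaporins, 6 fell and 22 were not called, with the same count adjusted over the list alone, and SIP2-1 (contig 17598) fell 1.90-fold. The aquaporin median was -0.42 (camera adjusted p = 0.00554, and adjusted p = 0.485 with an estimated correlation), and -0.27 without mycorrhizal replicate 1.

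Sugar and phosphate genes changed in both directions. The sugar transporter SWEET1a (contig 18666, 1256 bases), a uniporter at the membrane, fell 24.7-fold from 182 ± 36.9 to 7.32 ± 1.40 CPM (SD, n = 3; edgeR adjusted p = 9.16e-05), while SWEET2a (contig 608) rose 2.38-fold and the sucrose transporter SUT1 (contig 2740) 1.86-fold. Of 36 sugar transporters, 7 rose, 6 fell and 23 were not called (10 and 8 when adjusted over the list alone; camera adjusted p = 0.617). Sucrose synthase 2 (contig 950), which cleaves sucrose, fell 3.26-fold from 6318 ± 295.8 to 1941 ± 243 CPM, trehalose-phosphate phosphatase 2 (contig 7478) fell 3.50-fold and trehalase (contig 11256) rose 8.10-fold. Of 56 contigs of sucrose, trehalose and starch metabolism, 8 rose, 10 fell and 38 were not called (8 and 13 when adjusted over the list alone), and their median of -0.08 turned to 0.10 with library size alone (camera adjusted p = 0.638). Phosphate transporters 1-4 (contig 14313) and 1-8 (contig 948) rose 5.91-fold and 9.17-fold, and PHO1-2 (contig 3801) fell 2.40-fold. Of 56 phosphate and sulfate transport contigs, 7 rose, 7 fell and 42 were not called (10 and 9 when adjusted over the list alone), and their median of -0.11 turned to 0.08 with library size alone (camera adjusted p = 0.675). In glycolysis and the TCA cycle, 7 of 55 contigs rose, 5 fell and 43 were not called (7 and 6 when adjusted over the list alone; camera adjusted p = 0.638). There the median of -0.05 and the camera direction, down, differed in sign from the mean of 0.08, and the median was 0.12 with library size alone.

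Transcription factors of the WRKY, MYB, NAC and ERF families rose more often than they fell. Of 194 tested, 43 rose, 12 fell and 139 were not called (53 and 15 when adjusted over the list alone). NAM-2 (contig 17253), a NAC factor, rose 21.1-fold, WRKY75 (contig 20553) 14-fold and ERF021 (contig 7389) 7.46-fold, and the MYB factor RAX3 (contig 33310) fell 3.35-fold. Their median was 0.22 (camera adjusted p = 0.00849, and adjusted p = 0.485 with an estimated correlation), and 0.38 without non-mycorrhizal replicate 1. The call ended without non-mycorrhizal replicate 3, at camera adjusted p = 0.0875.

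Of 98 contigs in jasmonate and ethylene pathways, 15 rose, 13 fell and 70 were not called (18 and 17 when adjusted over the list alone; camera adjusted p = 0.675). Allene oxide synthase (contig 20243), of jasmonate synthesis, fell 3.09-fold, and a further member that fell, contig 3426, is a potassium channel. In the auxin, cytokinin and gibberellin list, 10 of 91 rose, 6 fell and 75 were not called (9 and 6 when adjusted over the list alone; camera adjusted p = 0.798). Its members included UDP-glycosyltransferase 85A1 (contig 2145), up 4.26-fold, and the auxin-binding protein ABP19a (contig 4469), down 4.75-fold. In abscisic acid and strigolactone pathways, 1 of 32 rose, 5 fell and 26 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.753). The strigolactone receptor D14 (contig 5410) rose 2.49-fold, abscisic stress-ripening protein 3 (contig 9179) fell 6.95-fold and ABI5 (contig 25679) fell 6.44-fold. The median of this list, 0.18, and its camera direction, up, differed in sign from its mean, -0.08. Of 30 symbiosis-related contigs, 5 rose, 5 fell and 20 were not called (7 and 6 when adjusted over the list alone; camera adjusted p = 0.877). Nodulation receptor kinase (contig 28062) fell 2.83-fold, and an acyltransferase (contig 22041) known from general lipid synthesis rose 2.72-fold. The pattern also caught a cell division cycle-associated 7-like protein, whose product name is not that of a symbiosis gene. It rose 2.0-fold in contig 16544 and fell 2.53-fold in contig 24968, and each call was lost on leaving out at least 1 library. Of 6 nodulin and blue copper contigs, 3 fell and 3 were not called (4 fell when adjusted over the list alone; camera adjusted p = 0.00653, and adjusted p = 0.485 with an estimated correlation). Chemocyanin (contig 63833), a small copper protein, fell 10.2-fold, or 15.4-fold without mycorrhizal replicate 3.

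The lists of cell wall, protease and fatty acid genes were lower in mycorrhizal roots. Of 139 cell wall contigs, 46 fell, 13 rose and 80 were not called (49 and 17 when adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.000514, and adjusted p = 0.485 with an estimated correlation). Endoglucanase 24 (contig 12006) fell 6.57-fold and fasciclin-like arabinogalactan protein 2 (contig 37996) 5.27-fold, while cellulose synthase-like protein D3 (contig 565) rose 19.3-fold. Of 88 proteases, 29 fell, 8 rose and 51 were not called (30 and 9 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.000514, and adjusted p = 0.485 with an estimated correlation). Among the contigs with unequal non-mycorrhizal levels, 9 of 30 are subtilisin entries of this kind. A subtilisin-like protease outside them (contig 13691) fell 3.62-fold from 185 ± 21.4 CPM. Of 17 contigs of fatty acid synthesis, 7 fell and 10 were not called (9 fell when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.000253, and adjusted p = 0.485 with an estimated correlation). The thioesterases FATB (contig 13960) and FATA (contig 9644), which release fatty acids from their carrier, fell 2.67-fold and 1.72-fold. Of 69 endodermis, suberin and xylem markers, 17 fell, 8 rose and 44 were not called (18 and 8 when adjusted over the list alone). Cellulose synthase A subunit 7 (contig 12442), of secondary walls, fell 9.82-fold, and scarecrow-like protein 32 (contig 8822), a general GRAS factor, rose 45.0-fold. Scarecrow-like protein 9 fell 2.27-fold from 410 ± 44.8 CPM in contig 771 and rose 4.22-fold from 1.52 ± 0.415 CPM in contig 13451, which has 363 bases. This list missed the threshold at camera adjusted p = 0.064, and passed at 0.0332, 0.0109, 0.015 and 0.0225 without non-mycorrhizal replicates 2 and 3 and mycorrhizal replicates 2 and 3, and at 0.0371 with a block on replicate number.

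The lists of photosynthesis genes, a marker of plastid-rich tissue, of ribosomal proteins and of reference genes were also lower. Of 53 photosynthesis contigs, 15 fell, 1 rose and 37 were not called (19 and 1 when adjusted over the list alone). A photosystem II 10 kDa protein (contig 7416) fell 5.78-fold and a photosystem I subunit (contig 20696) 3.39-fold. Their median was -0.56 (camera adjusted p = 0.000321, and adjusted p = 0.485 with an estimated correlation), and -0.85 without mycorrhizal replicate 3. Of 121 cytosolic ribosomal proteins, 16 fell, 3 rose and 102 were not called (14 and 3 when adjusted over the list alone), with L37a (contig 2475) and L21-2 (contig 1257) down 1.69-fold and 1.68-fold. Their median was -0.28 (camera adjusted p = 1.21e-05, and adjusted p = 0.605 with an estimated correlation), and -0.19 without mycorrhizal replicate 1. Of 70 reference genes, 19 fell, 4 rose and 47 were not called (20 and 6 when adjusted over the list alone; camera adjusted p = 0.000674, and adjusted p = 0.485 with an estimated correlation). Of 13 tubulin contigs, 9 fell, with a family median of -1.58, or -1.42 with library size alone. Actin-7 (contig 931) had a log2 fold change of 0.24 (edgeR adjusted p = 0.54), and polyubiquitin (contig 620) of -0.04 (edgeR adjusted p = 0.925), which was 0.14 with library size alone. Elongation factor 1-alpha (contig 347) had -0.996 (edgeR adjusted p = 0.0349), a call lost without non-mycorrhizal replicates 1, 2 and 3 (adjusted p of 0.0724, 0.0983 and 0.0889) and mycorrhizal replicates 1 and 3 (0.0708 and 0.0837). Of 85 heat shock proteins and chaperones, 4 rose, 4 fell and 77 were not called by edgeR. None of these passed when adjusted over the list alone, where 19 had an unadjusted edgeR p under 0.05, and the list had camera adjusted p = 0.801.

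With an estimated correlation, camera called none of the 29 lists. 2 lists, antioxidant enzymes and cell wall remodelling, had an unadjusted p under 0.05 there, and fry called 9 lists where camera at the preset correlation called 14. Fry lost 6 of the 14, at adjusted p of 0.0612 for peroxidases, 0.0595 for phenylpropanoid synthesis, 0.0542 for nitrogen transporters and for aquaporins, 0.153 for ribosomal proteins and 0.0638 for photosynthesis genes, and gained chitinases and beta-glucanases at 0.03. Of those 14 lists, 12 were lower and 2 higher in mycorrhizal roots.

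**Figure D3:**
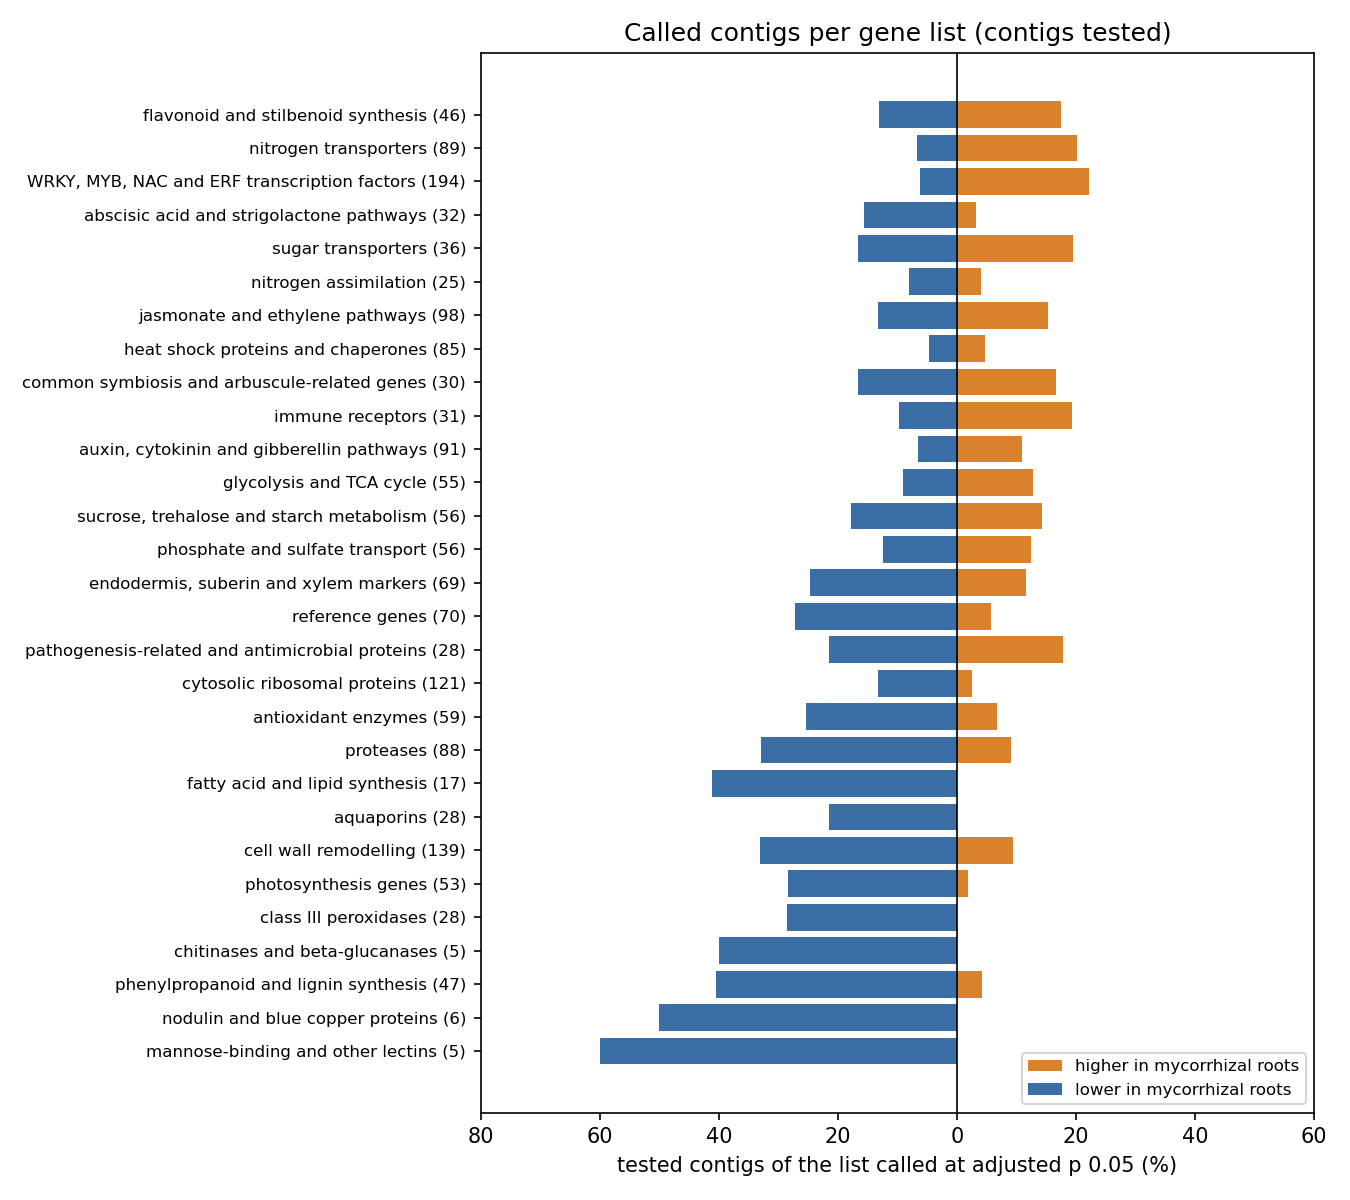
Percent of the tested contigs of each of the 29 lists that passed adjusted p 0.05 in edgeR, with contigs lower in mycorrhizal roots to the left of 0 and contigs higher to the right, and the number tested in parentheses. Bars to the left are longer for lectins (3 of 5), phenylpropanoid and lignin synthesis (19 of 47) and cell wall remodelling (46 of 139), and bars to the right for WRKY, MYB, NAC and ERF factors (43 of 194).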

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

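The uniquely mapped reads and the Gene Ontology tests were chosen after seeing the data. Counts of called contigs stayed within 1.5 times their value (2424 higher, 2573 lower) with DESeq2 size factors, the DESeq2 Wald test, limma-voom, no filter, 1 CPM in 3 libraries, TMM without fungal contigs, fungal contigs left out and unique reads. A like count need not mean the same contigs. Without a filter, 2423 were higher and 3461 lower, of which 1536 and 2374 were called in the main fit. With limma-voom, 1860 and 2368 were shared with the main fit. With library size alone, 3809 were higher and 1693 lower, because that scaling moves the median by 0.184. A 2-fold threshold left 1397 lower by its construction. Leaving out each library gave 789 to 2506 higher and 1150 to 2258 lower, with fewer samples in each fit. The groups came from different plants, so the main fit held no block on the numbers 1 to 3. Deviations from the group means correlated at 0.0593, 0.151 and -0.0516 between replicates of the same number. Between replicates of other numbers the values ran from -0.183 to 0.0885, and so few values cannot decide on pairing. A block on the numbers gave 2426 higher and 2270 lower, of which 2027 and 2133 were called in the main fit. The difference in fungal share, 0.0274 percentage points, was 0.0246 to 0.0319 without each library and 0.0601 over annotated contigs alone. These shares are not scaled by TMM, so the upward shift of 0.184 with library size alone enters them. The cause of what remains was not tested. Of 29 lists, camera called 14, or 14 to 15 without each library, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 9 with fry; the cause was not tested. Of 138 named contigs, 100 kept their direction and call in every alternative run for them and 0 reversed. The alternatives run for them were DESeq2 size factors, the DESeq2 Wald test, limma-voom, the block, no filter and each library left out. Library size alone was not among these. Summing isoforms did not apply, since contig names show none, nor did the pseudocount and filter for values other than counts. The simulated test recovered 25 of 100 contigs changed 2-fold. It changed 200 of 22632 contigs, where 4997 were called in the real data, so that recovery does not give the power of the real test.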

Other observations

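Chosen only after the results were seen were the added lists, the Gene Ontology terms, and the tests of library scaling, of shared reads, of genomic DNA, of tissue of another kind and of RNA of another organism.

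Contigs with lipid and secondary wall terms were called lower in mycorrhizal roots more often than expected. Of 42 contigs with the term fatty acid biosynthetic process, 16 fell, where 6.01 were expected (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted p = 0.00914). They include linoleate 9S-lipoxygenase 5 (contig 73), which oxidises linoleate and fell 6.52-fold from 2546 ± 1000 to 391 ± 117 CPM (SD, n = 3; edgeR adjusted p = 0.00357), and allene oxide synthase (contig 5224), which fell 4.92-fold (edgeR adjusted p = 0.00501). Of 56 contigs with the term sterol biosynthetic process, 23 fell, where 8.02 were expected (Fisher's exact adjusted p = 0.00049). Members of the sterol pathway itself were cycloartenol-C-24-methyltransferase (contig 3616, 1.80-fold) and 7-dehydrocholesterol reductase (contig 1870, 1.81-fold), while ketoacyl-CoA synthase 11 (contig 5430, 5.19-fold), of very-long-chain fatty acids, and annexin D1 (contig 106, 3.10-fold), a calcium-binding protein, carry the term too. Secondary cell wall biogenesis had 9 of 15 contigs lower, where 2.15 were expected (Fisher's exact adjusted p = 0.00749), among them cellulose synthase A subunit 9 (contig 12019, 2.72-fold) and laccase-22 (contig 37823, 5.41-fold). Lists of tissue markers went the same way, with 15 of 53 photosynthesis contigs lower (camera adjusted p = 0.000321, and adjusted p = 0.485 with an estimated correlation) and 17 of 69 endodermis, suberin and xylem markers (camera adjusted p = 0.064). A different mix of tissues in the sections was not tested for these terms. Fisher's exact test takes contigs as independent, though some products stand on several, such as laccase-22 (contigs 37823 and 30762). The p-values of the Gene Ontology terms can thus be too small.

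Tubulins were mostly lower in mycorrhizal roots, and transcription regulators were called higher more often than expected, though most were not called higher. The term microtubule-based process had 8 of 13 contigs lower, where 1.86 were expected (Fisher's exact adjusted p = 0.00914), with tubulin beta-2 (contig 906) down 4.82-fold and a tubulin beta-1 (contig 2661) down 11-fold. Here too the test takes contigs as independent, though tubulin alpha-2 stands on several (contigs 43082 and 58822). Regulation of transcription had 61 of 357 contigs higher, where 31.3 were expected (Fisher's exact adjusted p = 0.000205). Examples are a MYB4-like factor (contig 1984), up 10.3-fold, WRKY51 (contig 24808), up 5.54-fold, and MADS-box factor 16 (contig 3728), up 3.97-fold. Contigs with a fungal match that the filter left out, 441 in all, summed to 86.2 ± 38.9 CPM in mycorrhizal and 40.0 ± 31.6 CPM in non-mycorrhizal roots (SD, n = 3), and the libraries of the groups overlapped. Of 36 histones, 2 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.721), with a median of -0.05, or 0.13 with library size alone. Of 7 root meristem identity contigs, 1 rose, with the same count adjusted over the list alone (camera adjusted p = 0.384, fry adjusted p = 0.0399): AIL1 (contig 2850), an AP2-type factor, at 3.22-fold.

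Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real split with 4997. The highest of the other 9 gave 0 by edgeR, with 115 to 844 contigs at an unadjusted p under 0.05 against 8909 in the real split; other tools were not run on the splits. 10 splits are too few for a share under 0.05.

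Of 48 DNA replication contigs, 12 fell, 2 rose and 34 were not called (14 and 3 adjusted over the list alone; camera adjusted p = 0.00157, and adjusted p = 0.49 with an estimated correlation), with a median of -2.74 among the 12 and of -0.16 over the list, or 0.02 with library size alone. More dividing tissue in the non-mycorrhizal sections stays open: of 46 mitosis and cytokinesis contigs 5 rose, 5 fell and 36 were not called (5 and 6 adjusted over the list alone; camera adjusted p = 0.787), with a median of 0.0139, opposite in sign to the camera direction. The bound set beforehand against it, a median of -0.5 or higher, was met. The members spread widely, with an SD of 0.924 in log2 fold change, which is not the error of that median. They went both ways, with cyclin-A2-1 (contig 60670) down 6.18-fold and kinesin-like NACK1 (contig 723) up 2.08-fold, so the median does not speak for each of them. Reads of a transcript falling on another contig remain open too: summed by accession, the 5 replication contigs whose accession has several contigs had a median of -1.76 against -2.50, a ratio of 0.704, with 4 still lower, and so few contigs cannot decide it. Scaling distorted by the lectin does not account for the falls of the 12. Library size alone moves the median contig by 0.184, while the smallest of their drops was a log2 fold change of -0.661. With that scaling their median was -2.55, 0.932 times that with TMM. These values argue against scaling for the 12, which were picked for being lower. The median of the whole list met an earlier bound on it with neither scaling. It changed sign, as a shift of 0.184 makes a median of -0.16 do, so it decides nothing for the list.

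Retrotransposon polyprotein contigs rose in mycorrhizal roots: 85 of 180 were higher and 2 lower (110 and 5 adjusted over the list alone), with a median of 1.48 (camera adjusted p = 8.4e-17, and adjusted p = 0.49 with an estimated correlation), or 0.96 without mycorrhizal replicate 1, where 53 were higher. Together they took 0.22%, 0.178% and 0.211% of counts in non-mycorrhizal replicates 1, 2 and 3, and 0.55%, 0.277% and 0.235% in mycorrhizal replicates 1, 2 and 3. Reads shared between contigs are unlikely as the cause, since at least 99.12% of the counts on the 85 were uniquely mapped in every library. Reads of copies assembled into a single contig also count as unique, so the test cannot decide on those. That test replaced the median with unique reads, 2.09 against 2.06, which so few shared reads could not move. RNA of a fungus stays open. Of the higher contigs, 82.35% had reads in all 3 non-mycorrhizal libraries, but reads there do not mark a contig as plant. Elongation factor 3 (contig 28486), of fungi, had 7 reads in these libraries too. Contigs with a fungal match that the filter left out summed to 40.0 ± 31.6 CPM there and 86.2 ± 38.9 CPM in mycorrhizal roots (SD, n = 3). Genomic DNA in the mycorrhizal libraries may contribute: the share of counts on other contigs left out by the filter was 1.78 times as high there (2.06% in mycorrhizal replicate 1, and 1.01% in replicates 2 and 3), below the 4.25-fold rise of the median contig among the 85, and without mycorrhizal replicate 1 these were 1.32 times and 2.79-fold. Neither that nor a change of transcription with mycorrhiza, which was not tested, can be excluded.

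Among lower contigs of at least 5 CPM in non-mycorrhizal roots, 30 of the 74 at least 16-fold lower and 23 of the 2044 others had a log2 ratio of non-mycorrhizal replicate 1 over replicate 3 above 2.5, a bound chosen after the values were seen. RNA of another organism stays open: 0 of 191 tested ribosomal protein and reference gene contigs showed the pattern, but the upper 95% limit of 1.91% lies above the bound of 1%. Tissue of another kind in unequal amounts in the non-mycorrhizal sections stays open too: 39.19% of the 74 lay within 0.75 of a single ratio, but that grouping is what raised the idea, so it decides nothing. No list of marker genes named such a tissue, and a coordinated response that differed between the 3 plants was not tested.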
